A study of Mus musculus with 2 samples.

How the data were processed

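Single-cell transcriptomes were read from hepatic stellate cell isolates of mouse liver, with 1 library from healthy animals and 1 from animals given carbon tetrachloride (CCl4). The authors deposited, for each library, a filtered matrix of whole-number UMI counts per gene and cell barcode, with no normalisation. A UMI (unique molecular identifier) tags 1 captured RNA molecule, so a count stands for molecules and not for reads. Per the submitters' processing notes, the matrices were made with Cell Ranger 3.0.2 on the mm10 genome. Per the labels, polyadenylated RNA was sequenced and the cells were isolated by a published protocol for stellate cells of normal and fibrotic mouse livers, which enriches them by density. No cell annotation was used here, so every cell class named in the text was rebuilt from marker genes.

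The gene lists, the marker genes, the filters, the comparisons and the rule for naming genes were fixed before the data were examined. Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept. Of 3574 healthy barcodes, 2534 passed, and of 3775 CCl4 barcodes, 2499 passed. The mitochondrial limit was exceeded by 1038 healthy and 1274 CCl4 barcodes, and 233 and 587 had fewer than 300 genes, so many barcodes failed both limits. Scrublet, as built into scanpy, called 11 healthy cells (0.434%) and 6 CCl4 cells (0.240%) doublets, and these were removed, which left 2523 and 2493 cells. A caller that marks so few cells has not worked, so doublets remain in the data. For this reason 2 further treatments of doublets in stellate-like cells were added after seeing the data: leaving out the 10% with the highest doublet scores, and leaving out cells in which endothelial or immune markers held over 10% as many UMIs as stellate markers.

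Both libraries were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbours was partitioned by the Leiden method at resolution 1, which gave 33 clusters. A cluster was named after the marker set with the highest mean log2 fold over all other cells, computed with 20 CPM added to both. It stayed unnamed with fewer than 3 detected markers of that set (2-fold or more, with a UMI in 10% of its cells), with more markers of another class among its top 10 genes by fold, or with a median UMI count under 1/3 of its library's and none of its markers among those 10 genes. The 14 marker sets covered hepatic stellate, portal fibroblast, vascular smooth muscle, endothelial, macrophage, monocyte, neutrophil, dendritic, B or plasma, T or NK, hepatocyte, cholangiocyte, mesothelial and erythroid cells. Stellate cells were named from Lrat, Reln, Colec11, Ecm1, Des, Hgf, Rgs5, Pdgfrb, Hand2, Lhx2, Cygb, Vipr1, Dcn and Sod3, so these genes are no independent evidence on the class.

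For each library, raw counts were summed over the cells of a class and scaled to a common total (CPM). The ratio of CCl4 over healthy CPM was taken on a log2 scale with an exact conditional binomial 95% interval. Shares of cells carry exact Clopper-Pearson 95% intervals and counts of single sub-clusters exact Poisson ones. A gene counted as measured at 20 CPM or more in 1 or both libraries, and at least 2-fold was called higher or lower as a rule of size. Where a gene had a count of 0 in 1 library, its ratio was computed against 3 counts over the class and is a lower bound. These 3 counts correspond to 2.86 CPM in the healthy and 1.11 CPM in the CCl4 stellate-like cells, which held 1048137 and 2695793 UMIs. No test across libraries was run, because each group had 1 library. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. The 21 lists were collagens, matrix glycoproteins and proteoglycans, matrix processing and turnover, contractile cytoskeleton, TGF-beta signalling, retinoid handling and quiescent stellate cell genes, growth factors and receptors, cytokines and chemokines, acute phase and NF-kB, complement, interferon-stimulated, MHC class I, proliferation, p53 and senescence, immediate early and dissociation stress, cholesterol synthesis, glycolysis, ER folding and secretion, oxidative phosphorylation, antioxidant and xenobiotic response, and sex-linked genes. Several stellate markers also belong to the retinoid and quiescent list.

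Shares of cells with a UMI were compared after thinning each cell at random to 2000 UMIs, leaving out shallower cells. Stellate-like cells of each library were also clustered alone at resolution 0.5, with 0.3 and 1 as alternatives. List scores of thinned cells were correlated with Spearman's method, beside 1000 lists of random genes matched on mean level. The genes named in the stellate-like comparison were the 12 with the highest and the 12 with the lowest ratio among genes with at least 50 CPM in the library where they were higher. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, unnamed gene models, markers of other classes and genes 3 or more times as abundant in another class of that library were left out of that choice. The 2 highest and 2 lowest measured members of each list and 17 fixed genes were added. A few genes named by these rules are not reported here. Genes named for other classes, for the sub-clusters and for the unnamed matrix-rich cluster were chosen after their values were seen.

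The code for ratios, intervals, list percentiles and thinning was tested on simulated data with 200 genes changed. Of these, 98 at 2-fold and 98 at 4-fold were among the 6845 genes run. Counts were drawn at random from the mean profile of all healthy barcodes, with totals close to those of the stellate-like cells. They carry no variation between cells, so they check the code and not how well the intervals cover the real comparison. The intervals held the true ratio for 98.0% of genes simulated at 2-fold, for 99.0% at 4-fold and for 95.0% of unchanged genes. Of 200 unchanged lists, 2.5% fell outside the central 95% of random lists. A depth gap alone moved the simulated share of cells with a UMI by 50.7 percentage points without thinning and by 0 with it.

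Gene positions are whole-gene spans of the GENCODE M21 annotation of GRCm38, the assembly also called mm10, matched by gene ID for 30934 of 31053 genes. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Alternatives covered the cell filter, doublets, cluster resolution, a definition of stellate-like cells by each cell's own markers, the library total, the weight of cells, the CPM minimum and the thinning depth. Others were added after seeing the data. They were the unnamed matrix-rich cluster taken into the class, its largest cluster alone, a minimum of 3000 UMIs, the treatments of doublets above and subtraction of the hepatocyte profile. Reads were not analysed here.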

Results

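Hepatic stellate cells are the vitamin A-storing pericytes of the liver, and in injured liver they turn into contractile, collagen-producing myofibroblasts. To compare their sub-populations in healthy and fibrotic livers, stellate cell isolates of wild-type C57Bl/6 mice were profiled by droplet single-cell RNA sequencing. Mice of the fibrosis group had received carbon tetrachloride (CCl4), a hepatotoxin, at 1 µL per g body weight in 2 doses per week for 6 weeks. The healthy library held 3574 cell barcodes with 24637681 UMIs in total and a median of 4466.5 per barcode. The CCl4 library held 3775 barcodes with 27051074 UMIs and a median of 2046. After filtering, 2523 healthy and 2493 CCl4 cells remained, with medians of 5081 and 3077 UMIs. Each group had 1 library and no replicate, so no test across animals was possible, and every interval covers counting error only.

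Both isolates held mostly other liver cells beside hepatic stellate-like (HSC-like) cells. HSC-like cells made up 168 of the healthy cells (6.66%, 95% interval 5.72 to 7.70%) and 133 of the CCl4 cells (5.33%, 4.49 to 6.29%). Other settings gave 4.15 to 7.31% in healthy and 3.47 to 10.4% in CCl4, so which library had the higher share depends on them. Endothelial-like cells were the largest healthy class with 33.2% (31.3 to 35.1%) and made up 6.94% (5.97 to 8.01%) of the CCl4 cells. Hepatocyte-like cells made up 10.7% (9.48 to 11.9%) of the healthy and 43.9% (42.0 to 45.9%) of the CCl4 cells. Of the 1095 CCl4 cells of this class, 564 lay in cluster 1, with a median of 794 UMIs and 1.55% mitochondrial UMIs. Cluster 12, with 123 of them, had medians of 39747 UMIs and 14.9%. Whether the shallow barcodes held whole cells was not tested. T or NK-like cells were at 8.40% and 3.21%, and monocyte-like cells at 0.595% and 2.33%. Neutrophil-like cells were at 0.0793% and 0.923%. Macrophage-like cells, at 12.6% and 11.95%, and B or plasma-like cells, at 5.43% and 5.74%, differed by less than their counting intervals. Dendritic-like cells were at 2.34% and 1.40%, cholangiocyte-like cells at 1.35% and 0.441%, and mesothelial-like cells at 1.74% and 1.12%. No cluster was named portal fibroblast, vascular smooth muscle or erythroid, and 17.0% of the healthy and 16.7% of the CCl4 cells lay in unnamed clusters. Among the unnamed, cluster 19 held 8 healthy and 85 CCl4 cells, with Acta2, Cnn1, Myh11 and Tagln among its leading genes. Clusters 2 (289 and 57 cells) and 16 (6 and 96) had haemoglobin genes among theirs. These clusters had fewer than 3 detected markers, so smooth muscle or erythroid cells may be present without a name. The density step of the isolation, the UMI and mitochondrial limits and the depth gap can each set these class shares. Median UMIs of hepatocyte-like cells were 5034 and 1483, and those of HSC-like cells 5719.5 and 20531.

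**Figure D1:**
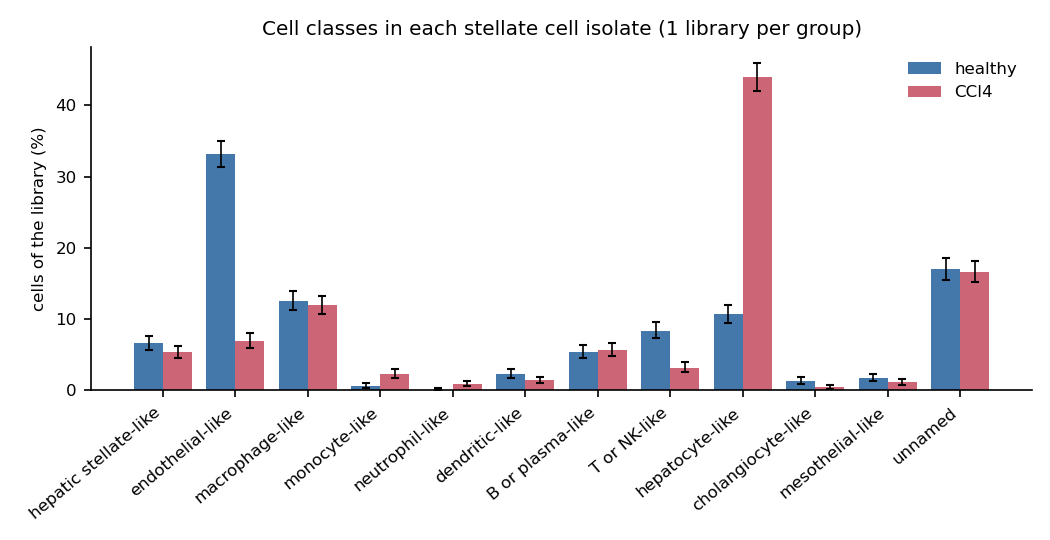
Share of each cell class among the filtered cells (y axis, percent) in the healthy and the CCl4 library, 1 library per group; error bars are exact 95% binomial intervals for counting error. Endothelial-like cells led the healthy isolate with 33.2%, hepatocyte-like cells the CCl4 isolate with 43.9%, and HSC-like cells were at 6.66% and 5.33%.

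HSC-like cells of the CCl4 library carried more RNA of most measured collagens and of 14 of 18 contractile cytoskeleton genes than those of the healthy library, and the median gene of retinoid handling and quiescence was lower. Acta2, the smooth muscle actin that marks myofibroblasts, was at 6.68 CPM in healthy and 551 CPM in CCl4 cells, 82.5-fold higher (95% interval 39.96 to 206). Col1a1 was at 70.6 and 3188 CPM, 45.2-fold higher (35.9 to 57.6), and Col3a1 at 749 and 6973 CPM, 9.31-fold higher (8.67 to 10.01). The opposite held for Ecm1, a secreted matrix protein of quiescent stellate cells, at 9313 and 1740.1 CPM, 5.35-fold lower in CCl4 (5.17 to 5.54). The median interferon-stimulated and MHC class I gene was also lower in CCl4, although most of these genes changed by less than 2-fold. These ratios rest on 1048137 UMIs of 168 healthy cells and 2695793 UMIs of 133 CCl4 cells. Most of the class came from different clusters in the 2 libraries: cluster 8 held 155 healthy and 13 CCl4 cells, and cluster 9 held 13 and 120. Of 7421 measured genes, 329 were at least 2-fold higher and 643 at least 2-fold lower in CCl4. The median log2 ratio of all measured genes was -0.18, and with the median of ratios in place of the library total the split became 472 higher and 463 lower.

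The matrix lists stood at the top of the matched random lists. Of 15 measured collagens, 9 were at least 2-fold higher in CCl4 and 0 were 2-fold lower, with a median log2 ratio of 2.003, or 2.18 relative to the median of all genes, at percentile 100 of 10000 random lists. Besides Col1a1 and Col3a1, Col1a2 was at 528 and 3508 CPM, 6.65-fold higher (6.10 to 7.26). Col15a1, with 3 healthy counts, had a log2 ratio of 3.61 (2.02 to 5.91). Col14a1, at 3165 and 2423 CPM, had a log2 ratio of -0.39 (-0.45 to -0.32), and Col16a1, at 106 and 105 CPM, one of -0.01, which was 0.17 with the median of ratios. Of 20 glycoproteins and proteoglycans, 10 were 2-fold higher and 0 lower, with a median of 0.92 (1.10 relative to all genes, percentile 100). The microfibril protein Mfap2 was 8.75-fold higher (4.67 to 18.5), and the fibulin Fbln1 had the same ratio with an interval of 3.30 to 32.8. With an unnamed matrix-rich cluster taken into the class, the log2 ratio of Fbln1 was 0.82 in place of 3.13. The laminin genes Lamb1 and Lama4 had log2 ratios of -0.36 and -0.34, and that of Lama4 was 1.88 without cells mixed with other classes.

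Of 19 genes of matrix processing and turnover, 10 were 2-fold higher and 1 was 2-fold lower in CCl4, with a median log2 ratio of 1.18 (1.36 relative to all genes, percentile 100). Lox, the enzyme that cross-links collagen, had 2 healthy counts and 50.1 CPM in CCl4, a ratio of 26.2 (7.13 to 219). The gelatinase gene Mmp2 was at 66.8 and 490.0 CPM, 7.34-fold higher (5.77 to 9.47), and the inhibitor gene Timp1 at 12.4 and 48.6 CPM, 3.92-fold higher (2.21 to 7.55). A single cell held 25.2% of the Timp1 UMIs in CCl4. Adamts1, a secreted protease, was the 2-fold lower member, at 479 and 194 CPM, and P4ha1, a collagen prolyl hydroxylase subunit, had a log2 ratio of -0.31. Of 18 contractile cytoskeleton genes, 9 were 2-fold higher and 0 lower, with a median of 0.74 (0.92 relative to all genes, percentile 99.99). Tagln, an actin-binding protein of smooth muscle, was at 143 and 1444 CPM, 10.1-fold higher (8.57 to 11.96). Acta2 UMIs came from 58 of the 133 CCl4 cells, and 1 cell held 20.5% of them. Actg1 had a log2 ratio of -0.25, and Cnn3 one of -0.14 that turned to 0.04 with the median of ratios.

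Genes of retinoid handling and quiescence were lower as a group. Of 21 measured members, 7 were at least 2-fold lower and 1 was 2-fold higher in CCl4, with a median log2 ratio of -0.63 (-0.45 relative to all genes, percentile 0.01). Members below 2-fold made up the other 13. Hhip, the decoy receptor of hedgehog ligands, was at 296 and 25.2 CPM, 11.7-fold lower (8.99 to 15.5), and the nerve growth factor receptor gene Ngfr was 2.69-fold lower (2.23 to 3.25). Hgf, the hepatocyte growth factor gene, was at 1120.1 and 600.2 CPM, 1.87-fold lower (1.73 to 2.01), and Reln at 2356 and 1524 CPM, 1.55-fold lower (1.47 to 1.62). Lrat, whose enzyme esterifies retinol for storage, was at 1833 and 1511 CPM, 1.21-fold lower (1.15 to 1.28). Against this trend Adamtsl2 was 2.62-fold higher (1.98 to 3.54). Lrat, Reln, Hgf, Ecm1 and Des helped to name the class. Des was at 276 and 329 CPM, and its log2 ratio of 0.25 lost its size when each cell's own markers defined the class. The platelet-derived growth factor receptor genes Pdgfrb and Pdgfra had log2 ratios of 0.17 and 0.13, which were -0.08 and -0.02 without cells mixed with other classes.

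Further genes with the highest ratios were Ajap1, Myof, Scube1, Ltbp2, Plat, Svep1, Tmem119, Vegfd and Fhl2. The latent TGF-beta binding protein gene Ltbp2 had 0 healthy counts and 92.7 CPM in CCl4, at least 32.4-fold higher, and the lymphangiogenic factor Vegfd 0 counts and 53.4 CPM, at least 18.7-fold higher. Scube1 was at 3.82 and 126 CPM, 33.1-fold higher (12.8 to 122), and Plat, the tissue plasminogen activator gene, at 5.72 and 165 CPM, 28.8-fold higher (13.1 to 79.0). Fhl2, a LIM-domain protein gene, was 15.3-fold higher (8.22 to 32.1). Ajap1, Myof, Svep1 and Tmem119 had 1 to 3 healthy counts and log2 ratios of 5.96, 5.18, 4.58 and 4.54. The ratio of Myof was 2.78 when each cell's own markers defined the class. The genes with the lowest ratios, besides Hhip and Ecm1, were Disp2, Gcgr, Fcna, Piezo2, Ntm, Epor, Cyfip2, Fam84a, Pde8b and Mgll. Disp2 was at 248 and 12.98 CPM, 19.1-fold lower (13.4 to 28.03), the glucagon receptor gene Gcgr 10.4-fold lower (6.53 to 17.2) and the mechanosensitive channel gene Piezo2 5.68-fold lower (4.41 to 7.36). Fcna, a ficolin of the lectin complement pathway, was at 1591 and 207 CPM, 7.70-fold lower (6.99 to 8.49), and healthy macrophage-like cells held 1975 CPM of it. Log2 ratios of the other 6 lay between -2.46 for Ntm and -2.10 for Mgll.

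**Figure D2:**
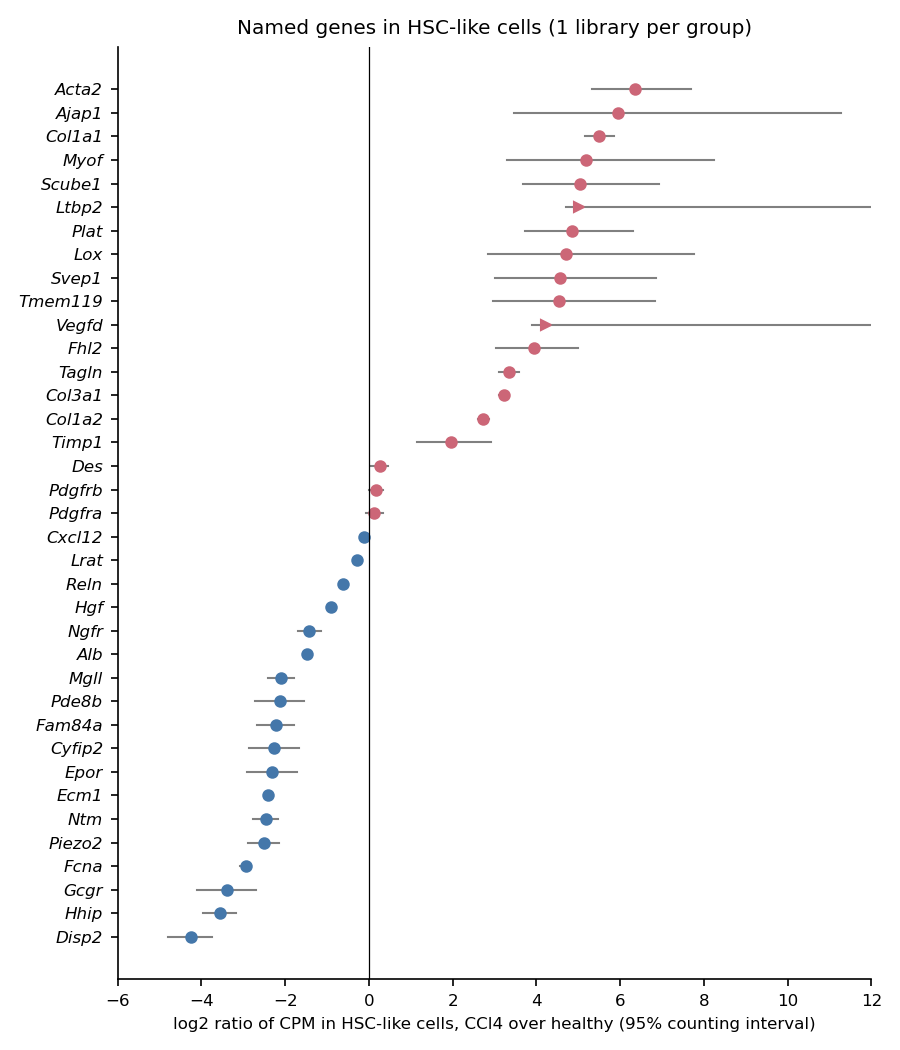
Log2 ratio of CPM, CCl4 over healthy, in HSC-like cells (x axis) for the named genes (y axis), with exact 95% intervals for counting error and 1 library per group. Ltbp2 and Vegfd had 0 healthy counts and are drawn as lower bounds with intervals open to the right. Acta2 is the highest point drawn, at 6.37, which the true ratios of Ltbp2 and Vegfd may exceed, and Disp2 the lowest, at -4.26.

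On mm10 (GRCm38), Acta2 (ENSMUSG00000035783) lies on chromosome 19 from 34241090 to 34255590 on the minus strand, and Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042 on the plus strand. Col3a1 (ENSMUSG00000026043) lies on chromosome 1 from 45311538 to 45349706, plus strand, and Lox (ENSMUSG00000024529) on chromosome 18 from 52516067 to 52529867, minus strand. Ecm1 (ENSMUSG00000028108) lies on chromosome 3 from 95734147 to 95739569, minus strand, and Hhip (ENSMUSG00000064325) on chromosome 8 from 79965851 to 80058006, minus strand. These are spans of whole protein-coding genes, since the counts are summed per gene.

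Interferon-stimulated genes were lower in CCl4 HSC-like cells, with 5 of 16 at least 2-fold lower, 0 higher and a median log2 ratio of -0.77 (-0.59 relative to all genes, percentile 0.01). The antiviral gene Rsad2 was 4.37-fold lower (2.73 to 7.11) and Ifi44 2.37-fold lower (1.69 to 3.32). Irf7 had a log2 ratio of -0.07, which was 0.11 with the median of ratios, and Ifi27l2a went the other way at 1251 and 1913 CPM. Of 10 MHC class I genes, 2 were 2-fold lower and 0 higher, with a median of -0.79 (-0.61 relative to all genes, percentile 0.06). The peptide transporter gene Tap2 was 2.18-fold lower (1.69 to 2.81) and H2-T23 2.03-fold lower (1.76 to 2.33), while B2m and H2-Q4 had log2 ratios of -0.15 each, which turned to 0.03 with the median of ratios. Cholesterol synthesis genes had a median of -1.05 over 6 measured members, 4 of them 2-fold lower (-0.87 relative to all genes, percentile 4.39). Insig1 was 2.86-fold lower (1.64 to 4.996), and Hmgcs1 had a log2 ratio of -0.84. Antioxidant and xenobiotic response genes had a median of -0.51 (-0.33 relative to all genes, percentile 1.42), with 1 of 15 2-fold higher and 2 lower. Gclc, of glutathione synthesis, was 2.97-fold lower (1.89 to 4.68) and Sod1 2.05-fold lower (1.72 to 2.44), whereas Gpx3 was 3.71-fold higher (2.59 to 5.49) and the metallothionein gene Mt1 1.44-fold higher (1.32 to 1.58).

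Acute phase and NF-kB genes lay above most random lists without a 2-fold member among 10, at a median log2 ratio of 0.36 (0.54 relative to all genes, percentile 98.5). Cebpd and Nfkbiz were 1.92-fold (1.72 to 2.15) and 1.90-fold (1.47 to 2.47) higher, and Steap4 and Icam1 had log2 ratios of -0.64 and -0.42. Immediate early and dissociation stress genes had a median of 0.43 (0.61 relative to all genes, percentile 99.4), with 1 of 19 at least 2-fold higher and 2 lower. Nr4a1, with 2 healthy counts, had a log2 ratio of 4.66 (2.78 to 7.72; 2.44 when each cell's own markers defined the class), Fosb was 1.79-fold higher (1.58 to 2.02), and Hspa1a and Ier3 had ratios of -1.93 and -1.18. Glycolysis genes had a median of 0.15 (0.33 relative to all genes, percentile 97.2) with 1 of 13 at 2-fold, the hexokinase gene Hk2, 3.40-fold higher (2.02 to 6.12). Gpi1, Pfkl and Hk1 had log2 ratios of 0.59, -0.75 and -0.33.

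TGF-beta signalling genes had a median log2 ratio of 0.06 (0.24 relative to all genes, percentile 94.97), with 4 of 20 at least 2-fold higher and 0 lower. Its lead was Ltbp2, followed by Tgfb3, with 2 healthy counts and a log2 ratio of 3.99 (2.10 to 7.06), and its lowest members were Eng and Tgfbr3 at -0.80 and -0.68. Proliferation genes were mostly below 20 CPM: of 5 measured members 2 were 2-fold higher and 0 lower (median 0.42, 0.60 relative to all genes, percentile 94.7). Cdk1 was at 5.72 and 21.9 CPM and Stmn1 at 9.54 and 28.9 CPM, and Pcna and Hmgb2 had log2 ratios of -0.80 and -0.18. When each cell's own markers defined the class, Cdk1, Stmn1 and Hmgb2 were at 3.80, 3.36 and 0.62. The unnamed cluster 25, with 12 healthy and 36 CCl4 cells, had Top2a, Mki67 and Stmn1 among its leading genes. Clustering thus drew dividing cells out of the named classes, and whether stellate cells were among them was not tested. For growth factors and receptors the median was -0.22 (-0.04 relative to all genes, percentile 20.9), with 2 of 18 higher and 4 lower. Igfbp7 was at 5099 and 11007 CPM, 2.16-fold higher (2.10 to 2.22), and Bmp10 2.70-fold lower (2.25 to 3.24). Igfbp5 was 8.04-fold lower (3.51 to 20.6), on UMIs of 3 cells in each library.

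Cytokines and chemokines had a median of -0.11 (0.07 relative to all genes, percentile 56.8) with 1 of 9 higher and 1 lower. Cxcl1 was 4.82-fold higher (1.96 to 15.4), Ccl2 1.95-fold higher (1.59 to 2.41) and Cxcl10 2.24-fold lower (1.89 to 2.66), and Il33 had a log2 ratio of -0.98. With the matrix-rich cluster taken into the class, the log2 ratio of Ccl2 was 0.25 in place of 0.96. A single cell held 24.8% of the CCl4 Cxcl10 UMIs. Cxcl12 was at 3755 and 3481 CPM, and its ratio of -0.11 turned to 0.07 with the median of ratios. Complement genes had a median of 0.05 (0.23 relative to all genes, percentile 66.4), with 0 of 8 higher and 1 lower. The inhibitor gene Serping1 was 1.90-fold higher (1.77 to 2.03) and C1s1 1.42-fold higher (1.22 to 1.65). Cd55, at 123 and 25.6 CPM, had UMIs in 14 healthy and 11 CCl4 cells, and its ratio of -2.27 turned to 1.06 without cells mixed with other classes. Cd59a had a ratio of -0.18, which was 1.75 without those cells. The p53 and senescence list had a median of -0.08 (0.10 relative to all genes, percentile 73.0), with 1 of 9 at least 2-fold higher and 2 lower: Phlda3 was 2.61-fold higher (2.01 to 3.43), Trp53inp1 was 1.69-fold higher (1.14 to 2.56), and Cdkn1a and Aen had log2 ratios of -1.59 and -1.12. Oxidative phosphorylation genes had a median of 0.02 (0.20 relative to all genes, percentile 82.1) and ER folding and secretion genes one of -0.23 (-0.05 relative to all genes, percentile 16.3), with 0 members of either at 2-fold. Sdhb, Sdha and Cycs had log2 ratios of 0.47, -0.49 and -0.29, and Ssr4, Sec61b, Hsp90b1 and Canx of 0.71, 0.43, -0.74 and -0.72. Of the sex-linked list, Xist was measured at 599 and 707 CPM and no Y-linked gene was.

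Markers of other cell types moved with the library as well. All 12 hepatocyte markers were lower in CCl4 HSC-like cells, at a median log2 ratio of -1.27, and Alb was at 2838 and 1010.5 CPM. Endothelial markers had a median of -2.24 over 12 genes and macrophage markers one of -3.24 over 4. Portal fibroblast markers had a median of 4.13 over 3 measured genes and smooth muscle markers one of 1.98 over 4, while the 14 stellate markers had one of -0.28. Of the monocyte, neutrophil and mesothelial sets 1 gene each was measured, and of the dendritic, B or plasma, T or NK, cholangiocyte and erythroid sets 0. Cells in which endothelial or immune markers exceeded 10% of the stellate marker UMIs numbered 23 of 168 healthy (13.7%) and 8 of 133 CCl4 (6.02%) HSC-like cells.

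Per cell, collagen RNA was near universal in CCl4 HSC-like cells, while Acta2 RNA was found in a minority. After thinning to 2000 UMIs, which left 129 healthy and 126 CCl4 cells and removed 39 and 7, Col1a1 was found in 9.30% (4.90 to 15.7%) and 92.1% (85.9 to 96.1%) of cells. Col1a2 was found in 65.1% and 97.6%, Col3a1 in 68.2% and 98.4%, and Tagln in 20.9% (14.3 to 29.0%) and 54.0% (44.9 to 62.9%). Acta2 was found in 1.55% (0.188 to 5.49%) and 25.4% (18.1 to 33.9%) of cells, and Lox in 0.775% and 9.52%. Timp1 was found in 1.55% and 7.14%, with overlapping intervals. Lrat was found in 95.3% (90.2 to 98.3%) and 84.9% (77.5 to 90.7%), Hgf in 85.3% and 58.7%, and Ngfr in 34.1% and 13.5%. Shares of Reln (92.2% and 92.1%), Des (44.96% and 43.7%), Pdgfrb (56.6% and 59.5%), Pdgfra (43.4% and 42.1%) and Cxcl12 (96.9% and 98.4%) differed by less than their intervals. Mki67 was found in 0 of 129 and 1 of 126 cells, with the dividing cells of cluster 25 outside the class. Unthinned, the shares were 13.7% and 94.7% for Col1a1, 76.2% and 97.7% for Col1a2, 74.4% and 98.5% for Col3a1, 31.5% and 83.5% for Tagln, 2.98% and 43.6% for Acta2, 1.19% and 41.4% for Lox and 3.57% and 41.4% for Timp1. They were 94.0% and 99.2% for Lrat, 83.9% and 94.0% for Hgf, 51.8% and 54.1% for Ngfr, 91.7% and 97.7% for Reln, 66.1% and 92.5% for Des, 72.6% and 94.0% for Pdgfrb, 66.7% and 91.7% for Pdgfra, 92.9% and 99.2% for Cxcl12 and 0.595% and 7.52% for Mki67, at median depths of 5719.5 and 20531 UMIs.

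As background, thinned endothelial-like cells (800 healthy and 162 CCl4, with 37 and 11 left out) held Col1a1 in 0% and 0.617%, Col3a1 in 0.125% and 3.09%, Acta2 in 0% of both and Lrat in 0.250% and 0.617%. Thinned macrophage-like cells (168 and 165, with 149 and 133 left out) held Col1a1 in 0% and 1.21%, Col3a1 in 0.595% and 5.45%, Acta2 in 0% of both and Lrat in 4.17% and 1.21%. The share for Lox was 2.42% in CCl4 macrophage-like cells. Hgf was found in 15.2% and 31.5% of endothelial-like cells, a class that expresses it. Before thinning, median depths were 7479 and 13284 UMIs in endothelial-like and 2293 and 2360 in macrophage-like cells.

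**Figure D3:**
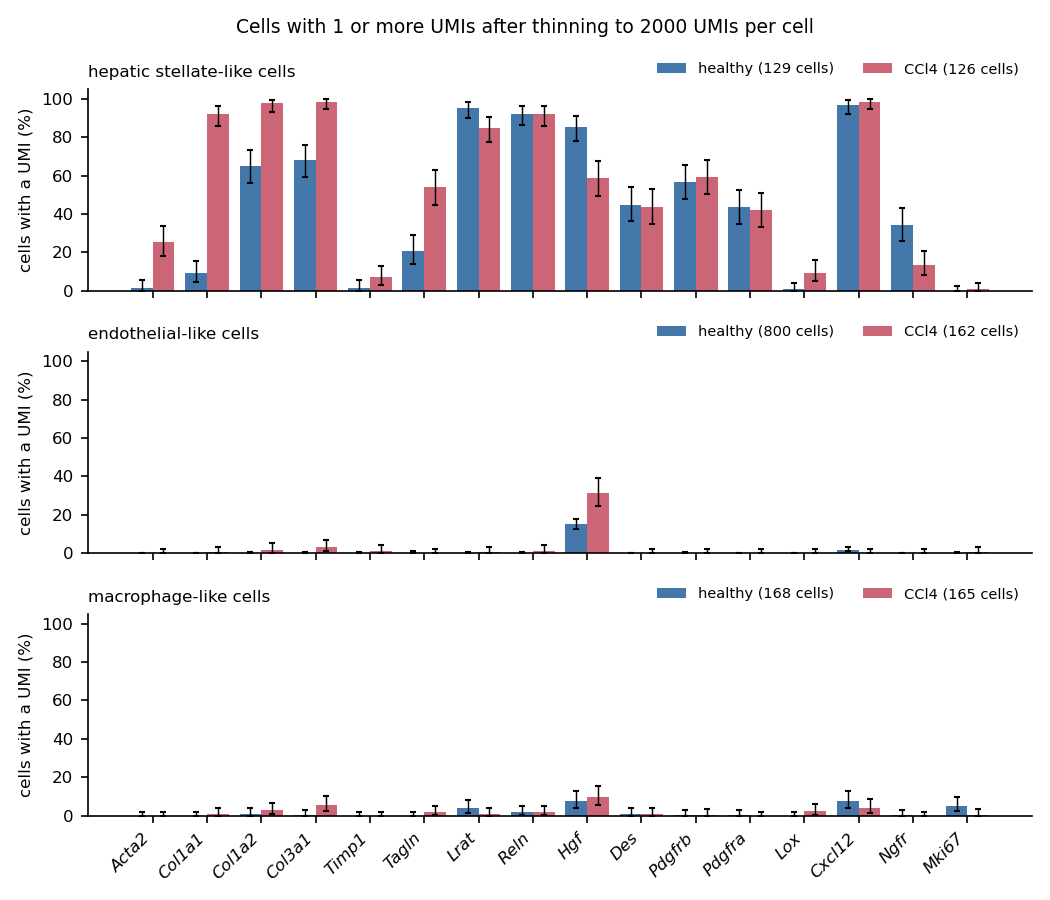
Share of cells with 1 or more UMIs of each gene (y axis, percent) after thinning to 2000 UMIs, in HSC-like, endothelial-like and macrophage-like cells of the healthy and the CCl4 library; error bars are exact 95% binomial intervals for counting error. Col1a1 was in 9.30% of healthy and 92.1% of CCl4 HSC-like cells, and at most 1.21% of the cells of the other classes.

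Within the CCl4 library, contractile and collagen RNA peaked in different sub-clusters of HSC-like cells at resolution 0.5, and in the same one at the alternative resolution 0.3. Clustered alone, the class gave 3 sub-clusters of 48, 45 and 40 cells, numbered 0, 1 and 2. Sub-cluster 2 was led by Mest, Acta2, Ccl2, Actg2 and Tagln, sub-cluster 1 by Ackr4, Col3a1, Nnat, Adamtsl2 and Col1a1, and sub-cluster 0 by Igfbp4, C4b, Fabp4 and Wt1. The leading genes define the sub-clusters and are given as such. All the same, Acta2 was detected in each, at 148 CPM (95% Poisson interval 126 to 173) in sub-cluster 0, 259 CPM (226 to 296) in 1 and 1410.2 CPM (1328 to 1496) in 2, and Col1a1 was at 3555, 4754 and 1009 CPM. Contractile genes took 0.938%, 1.08% and 2.14% of UMIs, and collagens 1.87%, 2.96% and 1.55%. The leading genes Acta2, Tagln, Col1a1 and Col3a1 belong to these lists, so the shares are no independent evidence of separate peaks. At resolution 0.3, which gave 2 sub-clusters, 1 of them held more of both, with collagens at 2.30% against 1.85% and contractile genes at 1.60% against 0.945% of UMIs. The other was led by endothelial genes such as Ptprb and Kdr, and Col1a1 itself was higher there, at 3469 against 2997 CPM. Lrat, not a leading gene, was at 1089, 1792 and 1779 CPM, Reln at 1380, 1732 and 1497 CPM, Rgs5 at 477, 1570 and 2205 CPM and Dpt at 629.6, 303 and 29.2 CPM. Across the 126 thinned cells, collagen and contractile scores had a Spearman correlation of 0.11, inside the range of -0.20 to 0.21 for random lists.

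Healthy HSC-like cells gave 4 sub-clusters. Sub-cluster 0 (69 cells, median 1920 UMIs) was led by hepatocyte genes with Alb at 7964 CPM, and sub-cluster 3 (13 cells) by endothelial genes with Stab2 at 1112 CPM, so neither was named. Sub-clusters 1 (45 cells) and 2 (41 cells) were led by Ccl2 and Mest, and by Mgp and the antigen presentation gene Cd74 with other immune genes. Ngfr and Adamtsl2, described in mouse stellate cells near the portal and the central vein, lay apart in these 2 sub-clusters at resolution 0.5. Ngfr was at 386 CPM (314 to 470) in sub-cluster 1 and 146 CPM (111 to 187) in 2. Adamtsl2 was at 7.80 CPM (0.945 to 28.2) and 90.7 CPM (64.2 to 125). Sub-cluster 0 held Ngfr at 282 CPM and Adamtsl2 at 44.3 CPM, and sub-cluster 3 held them at 98.7 and 41.6 CPM. At resolution 0.3 the gap was smaller. Sub-clusters of 81 and 74 cells then held Ngfr at 225 and 314 CPM and Adamtsl2 at 65.9 and 24.6 CPM. In CCl4, Ngfr was at 37.6 CPM (26.9 to 51.3), 54.4 CPM (39.8 to 72.5) and 170 CPM (143 to 202) in sub-clusters 0, 1 and 2, and Adamtsl2 at 155 CPM (132 to 181), 233 CPM (201 to 268) and 20.3 CPM (11.6 to 33.0). Adamtsl2 was a leading gene of sub-cluster 1 there, so its difference is no independent evidence. At resolution 0.3 the 2 CCl4 sub-clusters held Adamtsl2 at 133 and 151 CPM and Ngfr at 112 and 37.5 CPM. Of 30 correlations between list scores, 2 lay outside their 95% random range, which chance alone can give: collagens against immediate early genes in healthy cells (-0.36, random range -0.31 to 0.23) and retinoid against interferon-stimulated genes in CCl4 cells (0.39, -0.22 to 0.23).

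**Figure D4:**
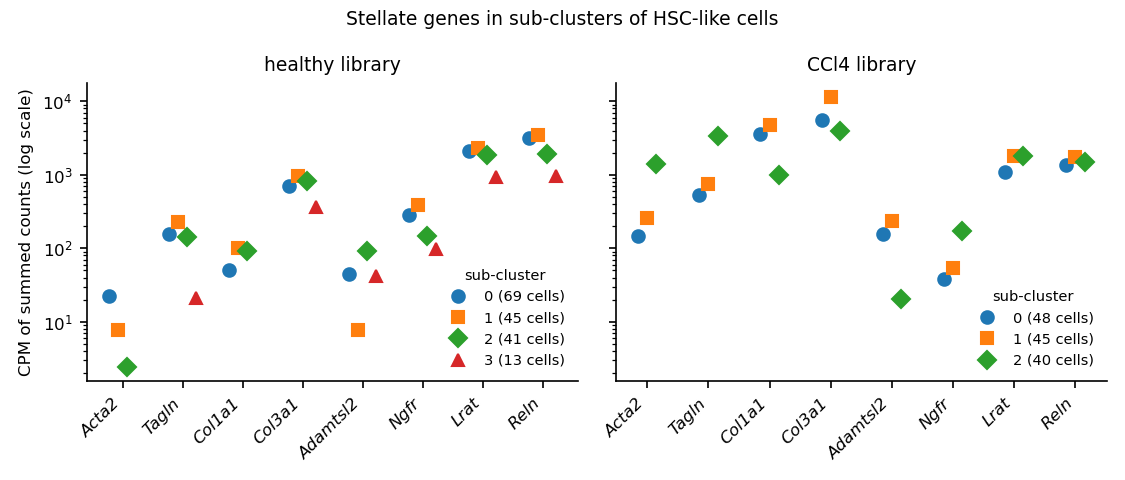
Level of 8 genes (x axis) as CPM of summed counts on a log scale (y axis) in sub-clusters of HSC-like cells, each library clustered alone; each point is 1 sub-cluster and counts of 0 are not drawn. In CCl4, Acta2 was highest in sub-cluster 2 (1410.2 CPM) and Col1a1 in sub-cluster 1 (4754 CPM), each a leading gene that helped to define its sub-cluster. Sub-cluster 2 of that library had the highest Ngfr (170 CPM) and the lowest Adamtsl2 (20.3 CPM) of its 3 sub-clusters. Adamtsl2 was a leading gene of sub-cluster 1, and at resolution 0.3 it was at 133 and 151 CPM in the 2 CCl4 sub-clusters.

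Other classes with at least 50 cells in both libraries were compared in the same way, relative to the median of all measured genes of each class. Endothelial-like cells of the CCl4 library carried more RNA of the type IV collagen genes Col4a1 and Col4a2 and, mostly by less than 2-fold, of contractile cytoskeleton genes. Col4a1 was at 589 and 1091 CPM and Col4a2 at 252 and 485 CPM. With Col5a2, at 18.995 and 73.6 CPM, they were the 3 measured collagens (median 0.96 above that of all genes, percentile 99.99). All 14 measured contractile genes had ratios above 0, 2 of them at least 2-fold (median 0.39 relative to all genes, percentile 100), while the laminin gene Lama4 had a log2 ratio of -0.17 (-0.35 to -0.01). The connective tissue growth factor gene Ctgf was at 14.5 and 173 CPM, a log2 ratio of 3.58 (3.24 to 3.93), and Cd34 at 14.8 and 129 CPM. The endothelial-like class joined cluster 0, with 756 healthy and 139 CCl4 cells, and cluster 15, with 81 and 34, so its make-up differed between the libraries. Macrophage-like cells of the CCl4 library carried less RNA of the Kupffer cell genes Clec4f (4879.9 and 603 CPM), Timd4 (390.4 and 112 CPM) and Vsig4 (2677 and 877 CPM), and more of Ccr2 (33.7 and 231 CPM), a receptor of recruited monocytes, Marco (269 and 1668 CPM) and Spp1 (2.07 and 45.2 CPM). Clec4f, Timd4, Vsig4 and Marco belong to the macrophage markers and Ccr2 to the monocyte markers used for naming. Different clusters held these cells: cluster 4 held 203 healthy and 35 CCl4 cells, cluster 13 held 15 and 105, cluster 26 held 0 and 48, and cluster 6 held 99 and 110.

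The median of interferon-stimulated genes relative to all genes was -0.74 in endothelial-like cells (1 of 14 genes 2-fold lower), -1.03 in macrophage-like (10 of 16), -1.22 in T or NK-like (6 of 9), -0.61 in B or plasma-like (2 of 6) and 0.20 in hepatocyte-like cells (0 of 5, 1 higher). Most measured endothelial markers were lower as well, with Ptprb at log2 ratios of -3.35 in B or plasma-like and -2.01 in T or NK-like cells. Pecam1 was the exception, at 0.32 (-0.22 to 0.88) and 0.94 (0.12 to 1.75). RNA of other cells thus differed between the libraries in these classes. T or NK-like cells were spread differently over clusters in the 2 libraries, since cluster 7 held 158 healthy and 32 CCl4 cells and cluster 23 held 36 and 35. MHC class I genes had medians of -0.74 in endothelial-like, -0.51 in macrophage-like, -0.16 in T or NK-like, -0.14 in B or plasma-like and 0.32 in hepatocyte-like cells. B or plasma-like cells of the CCl4 library held the antibody joining chain gene Jchain at 10579 CPM, with 0 counts in healthy (a log2 ratio of at least 10.69), and the secretory regulator Xbp1 at 49.1 and 315 CPM. Cluster 3 made up this class, and its marker set, with Jchain among it, covers both B and plasma cells. Their mix may therefore differ between the libraries, which was not tested. ER folding and secretion genes had a median of 0.43 relative to all genes in that class (percentile 99.96) and of -0.61 in hepatocyte-like cells (percentile 0). Oxidative phosphorylation genes of hepatocyte-like cells had one of 0.58 (percentile 99.97), and the metallothionein genes Mt1 and Mt2 were at 629.9 and 3041 CPM and at 113 and 782 CPM. Hepatocyte-like cells also came from different clusters, since cluster 17 held 102 healthy and 0 CCl4 cells and cluster 12 held 0 and 123.

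**Figure D5:**
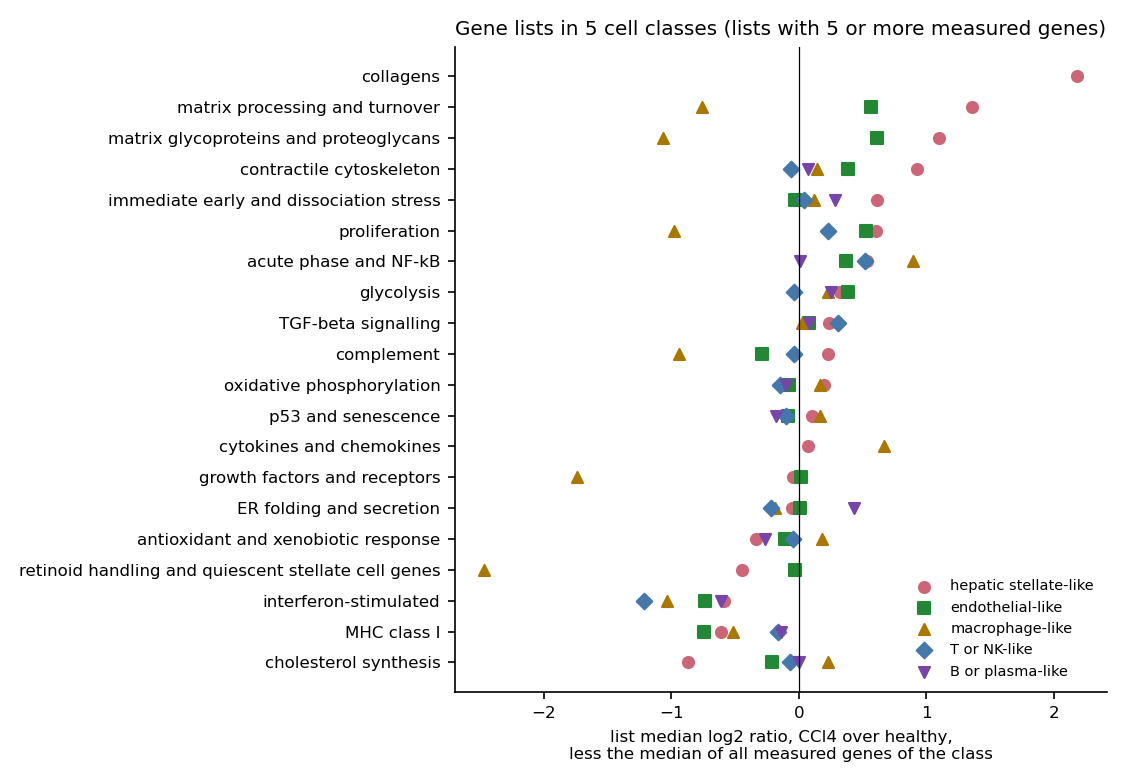
Median log2 ratio of each gene list, CCl4 over healthy, less the median of all measured genes of the class (x axis), for lists with 5 or more measured genes (y axis) in 5 cell classes, each point being 1 list in 1 class and 1 library per group. Interferon-stimulated genes lay below 0 in HSC-like, endothelial-like, macrophage-like and T or NK-like cells, and collagens of HSC-like cells at 2.18. Hepatocyte-like cells are not drawn.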

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

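All 4 tests of the matrix-rich cluster below were chosen only after the result was seen. Several lists went in opposite directions in HSC-like cells and in another class. In macrophage-like cells the collagens had a median log2 ratio of -1.35 over 4 measured genes, matrix glycoproteins and proteoglycans of -1.29 over 6 and matrix processing genes of -0.98 over 7, while these lists were higher in CCl4 in HSC-like cells. Among the 4 collagens, Col3a1 had a ratio of 0.71. In the same macrophage-like cells the stellate markers Dcn, Lrat and Reln had ratios of -3.19, -3.13 and -4.15 and the endothelial markers Ptprb and Stab2 of -4.17 and -2.14, so markers of other cell types were lower in this class as well. Retinoid handling and quiescent stellate cell genes had a median of 1.26 over 4 measured genes in hepatocyte-like cells and were lower in HSC-like cells. Stellate and matrix genes were higher still in hepatocyte-like cells: collagens had a median of at least 5.47 over 6 genes, 2 of them with 0 healthy counts, Dcn a ratio of 3.82 on 35 and 872 counts and Reln of 2.98 on 13 and 181, so genes of another cell type differed between the libraries in this class. These differences between classes were not tested.

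Stellate transcripts were also found outside the class. Among barcodes left out by the cell filter, 14 healthy and 7 CCl4 barcodes held UMIs of 5 or more stellate markers. The matrix-rich cluster, with 109 CCl4 cells, was outside the HSC-like class of the report except where an alternative took it in, because portal fibroblast markers outnumbered stellate markers among its leading genes.

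The matrix-rich cluster held stellate transcripts together with part of the portal fibroblast set. After thinning, Dpt, Mfap4 and Eln were found in 95.4%, 41.3% and 50.5% of its 109 cells. Dpt and Eln were also found in 31.7% and 19.8% of CCl4 HSC-like cells. Of the same set, Thy1 and Pi16 were found in 0 of the 109 cells, Entpd2 in 1 and Clec3b in 3. Free RNA would bring the stellate transcripts to other classes too, but their median level in endothelial-like cells was 0.00355 of that in the cluster. Doublets with HSC-like cells would bring all genes of these cells. Over 181 such genes other than Rgs5 the 10th percentile of the fraction was 0.658 of the median fraction of stellate markers (46.6%). Some of the 181 were higher in the cluster itself, such as Eln at 501%, so this percentile is a weak test. Rgs5 was at 3.01% of its level in HSC-like cells, which goes against doublets drawn evenly from these cells. So do 3 of the 181 genes, Angptl6, Plvap and Tnfrsf11b, at 4.13%, 6.78% and 6.92%. As these values and the percentile disagree, doublets stay open. Doublets with cells of a single CCl4 sub-cluster were not tested. Rgs5 was at 477 CPM in sub-cluster 0 and 2205 CPM in sub-cluster 2, and Tnfrsf11b was a leading gene of sub-cluster 2. Portal fibroblasts alone, without stellate genes, would lack Lrat, which 65.1% of the cells held after thinning, against at most 1.21% of endothelial-like and macrophage-like cells. A mix of separate cells would keep Lrat and Mfap4 apart, yet 30 cells held both where independent detection gives 29.3, a ratio of 1.02. Also open are a stellate-related matrix-producing state of fibrotic liver and fibroblasts that express Lrat themselves.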

How the results depend on the processing

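No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. Settings numbered 15 planned and 6 added after seeing the data. Of 137 values of the main results under them, 108 stayed within their limits and 29 moved. Of 979 other values, 207 moved. Over 17 settings the median log2 ratio kept its sign for collagens (1.62 to 2.18), matrix glycoproteins (0.74 to 1.16), matrix processing (0.76 to 1.36), contractile genes (0.37 to 1.04), retinoid and quiescent genes (-1.11 to -0.28), interferon-stimulated genes (-1.14 to -0.59) and MHC class I genes (-1.11 to -0.61). The p53 list kept its sign in 9 of 16 and the proliferation list in 15 of 16 (-0.49 to 3.36). TGF-beta signalling and the cytokines and chemokines each kept theirs in 16 of 17, and complement and oxidative phosphorylation each in 15 of 17.

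The HSC-like share was 4.15% in healthy and 3.47% in CCl4 without a cell filter and 5.67% in healthy at Leiden resolution 2. In CCl4 it was 9.34% with the stricter filter, 10.4% at resolution 0.5, 8.58% by each cell's own markers and 9.71% with the matrix-rich cluster, so whether the share was higher or lower in CCl4 depends on these choices. Genes 2-fold higher and lower numbered 803 and 1215 with thinned cells, 677 and 1270 at 5 CPM, and 126 and 156 at 100 CPM, where fewer genes are counted.

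Medians that moved were, with the median of ratios, 2.18 for collagens, 1.36 for matrix processing and 0.92 for contractile genes, by construction the shift of all genes. With thinned cells they were 1.62, 0.83 and 1.04. At 100 CPM they were 0.74 for glycoproteins, 0.76 for processing and 0.46 for contractile genes, and at 5 CPM -0.28 for retinoid genes. By each cell's own markers they were 1.16 for glycoproteins and -0.93 for retinoid genes. Retinoid genes were at -1.11 at resolution 0.5 and -1.07 with the matrix-rich cluster, contractile genes at 0.37 with the stricter filter, and collagens at 1.71 without mixed cells. Cd55 reversed to 1.06 without mixed cells. Except where stated, the cause was not tested.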

Other observations

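Of the tests in this part, those of free RNA, of animal or batch and of sequencing depth were chosen only after the result was seen, as were the genes named in this paragraph. The unnamed matrix-rich cluster of the CCl4 library was compared with HSC-like cells of the same library. Of 10 portal fibroblast markers 5 were measured, and the cluster carried more RNA of these (median log2 ratio 2.33). Such markers outnumbered stellate markers among its top 10 genes, which left it unnamed, so the naming rule in part set this difference. The cluster carried less of the cytokine and chemokine list (median -1.31) and of the retinoid and interferon-stimulated lists. Endothelial markers were lower in it too (median -1.47, 11 of 12 at least 2-fold), so HSC-like cells held more endothelial RNA than the cluster did. Col1a1 was at 3188 CPM in HSC-like cells and 7139 CPM in the cluster, Dpt at 352 and 1247 CPM, the elastin gene Eln at 121 and 604 CPM and the Wnt inhibitor gene Sfrp1 at 2.23 and 166 CPM. Rgs5, a gene of pericytes, was at 1325 and 39.8 CPM, whereas Pdgfrb, another one, was at 453 and 549.6 CPM. Acta2 was at 551 and 261 CPM and Ccl2 at 207 and 20.8 CPM. Retinoid and quiescent genes had a median log2 ratio of -1.57, interferon-stimulated genes of -1.11, MHC class I genes of -0.87 and collagens of 0.14, all over HSC-like cells.

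The median interferon-stimulated gene was lower in CCl4 in HSC-like cells and in 4 of the 5 other classes compared. Free RNA rich in these transcripts in the healthy library adds to each cell at most the UMIs found in B or plasma-like cells, and with those taken from healthy HSC-like cells the list was at -0.53 relative to all genes (counting range -0.65 to -0.39). Without the 10% of HSC-like cells with the highest list share it was at -0.60 (-0.79 to -0.49), and since both ranges cross the limit of -0.5 set for the tests, free RNA and a few responding cells stay open. With 1 library per group, an effect of CCl4 and one of animal, batch or housing cannot be told apart.

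HSC-like cells of the CCl4 library held 3.59 times the UMIs of healthy ones, and deeper sequencing would raise every class alike. Among the other classes with at least 50 cells in both libraries the highest ratio, in endothelial-like cells, was 0.495 of that, while smaller classes differed more, with medians of 1310 and 8063 UMIs in 44 and 28 mesothelial-like cells and of 5218 and 10301 in 15 and 58 monocyte-like cells. Without 23 healthy and 8 CCl4 cells mixed with endothelial or immune markers the ratio was 3.76 (5380 and 20245 UMIs). Among cells with at most 5% mitochondrial UMIs it was 2.89 (7303 and 21093 UMIs). That value argues against damage that raises the mitochondrial share as the whole cause. Damaged healthy cells with a low mitochondrial share would pass this limit, so they stay open. A higher RNA content of stellate cells in fibrotic liver stays open as a hypothesis, as do animal, batch and untested doublets of stellate cells with each other, with hepatocytes or with the matrix-rich cluster.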
